A study of Mus musculus with 4 samples.

How the data were processed

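Single-cell RNA sequencing was done on cells of mouse embryonic heart ventricles at day 12.5. Per the labels, an endothelial inducible Cre (Cdh5-CreER) was induced with tamoxifen at day 9.5, and the embryos carried 1 floxed Gata4 allele beside a normal one (here het) or 2 floxed alleles (here KO), with a Rosa26 reporter that switches from a red membrane protein to membrane EGFP. Each group had 2 libraries, and the labels do not say whether a library was 1 embryo or a pool. The labels conflict on the kit, naming 3′ v2 chemistry in 1 place and a later kit in another.

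The deposited matrices held raw UMI counts per gene and barcode, per the file headers, and every stored value was a whole number. The headers named Cell Ranger 6.0.1. The submitters' processing notes named mm10, Cell Ranger and Seurat. The matrices held 55405 genes, among them 4 added sequences (EGFP, dsRed, FloxGata4 and FloxGata4_ctrl), and 110 symbols stood on more than 1 row. The labels do not say what the FloxGata4 and FloxGata4_ctrl sequences hold. Gene identifiers and GRCm38 positions were taken from GENCODE M21, which may not be the annotation the authors used.

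The 4 matrices held 156491597 and 190207638 UMIs (het replicates 1 and 2) and 171252072 and 137890971 UMIs (KO replicates 1 and 2). Barcodes with fewer than 500 genes or with at least 20% mitochondrial UMIs were left out. Doublets were scored in each library with Scrublet (expected rate 0.1) as built into scanpy 1.11.5. Its automatic threshold failed in het 1 and KO 2, where it called 2 and 1 doublets, so the median of the thresholds that worked, 0.346, was used for both; this choice was made after the scores were seen. Doublets removed numbered 305, 243, 403 and 63 in het 1, het 2, KO 1 and KO 2.

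Counts were scaled to 10000 per cell, with globin UMIs left out of the cell total, and log-transformed. From genes seen in at least 20 cells, 2000 variable genes were chosen across libraries, leaving out Gata4, Xist, Tsix, Y-linked genes, globin genes and the added sequences. Each gene was centred and scaled within its library, and 30 principal components and 20 neighbours gave a shared-neighbour graph, which was partitioned by Leiden modularity in igraph 0.11.9 at resolution 1. A cluster was named for a cell type when the mean log2 fold of that type's fixed markers was at least 1, at least 3 of them were detected, and a marker of its own stood among its 10 leading genes. Clusters were also kept out of a class when cardiomyocyte markers took 1% or more of their UMIs, and a cardiomyocyte-like cluster needed at least 5%. Those limits on cardiomyocyte markers were set after the clusters were seen. Of 41 clusters, 23 were named and 18 were not.

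UMIs were summed per library and class for classes with at least 50 cells in each library. Genes passing filterByExpr (minimum count 10, minimum total 15) were normalised by TMM and tested with the quasi-likelihood fit of edgeR 4.0.16 in R 4.3.3, KO against het, 2 libraries against 2, with Benjamini-Hochberg adjustment at 0.05. Levels are CPM, UMI counts over the class total of the library scaled by TMM, with SD over 2 libraries; SE is that of the log2 difference. Ddx3y, Xist, EGFP and the FloxGata4 sequences are given as CPM without TMM. The effect in endothelial-like cells minus that in cardiomyocyte-like cells was tested as an interaction with library as a block. In all, 31 gene lists were fixed before the data were examined, as were the groups, the tests, the thresholds and most alternatives. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at the preset correlation of 0.01, and again with an estimated correlation and with fry. List members were also adjusted over the list alone. That adjustment takes no account of the 31 lists or of the number of classes. A member that rose or fell over its list alone is thus not called changed over all genes. Class shares were compared by a two-sided exact permutation test, whose smallest p is 0.333 with 2 libraries against 2, so it cannot pass 0.05. Single-library shares carry 95% Wilson intervals, which cover counting error only. The p-values of genes and shares measure spread between these libraries and nothing wider. Camera at the preset correlation sets the genes of a list against all other genes and takes genes as nearly independent. Its p-values rest on spread among genes and do not measure spread between libraries.

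Genes were named by a fixed rule: Gata4 in every class; among genes past the adjusted threshold with at least 20 CPM and libraries apart, the leading 10 per direction in endothelial-like cells and fewer in the other classes; up to 4 members of lowest p in each list described; and 5 per direction for the interaction. Sex-linked, globin, mitochondrial, ribosomal and unnamed genes were not eligible. No gene passed the adjusted threshold, so the part on that threshold named none. Neil2, Dkk1, Emb, Fbn2, Thsd7a, Rasgrp2, Ptpre, Col13a1, Dpp4 and Gata6 in endothelial-like cells, Mt3, H3c2 and Mfap2 in cardiomyocyte-like cells, Cxcl12 and Tnxb in mesenchymal-like cells, and H3c3, Igf1 and Vcan in epicardial-like cells fall outside the rule and were chosen after their values were seen. So were all genes of cluster 14, since that comparison was added after the clusters were seen, and genes named because a count held 5 or fewer.

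Alternatives were DESeq2 1.42.0 and limma-voom on the same sums, DESeq2 size factors within edgeR, no count filter, a stricter cell filter (1000 genes, 10% mitochondrial), doublets kept, resolutions of 0.5 and 2, equal depth, the replicate number as a block, other choices of endothelial clusters, transcripts of other cells left out, and each library left out in turn. Cells of at least 5000 UMIs, shares over named cells, the addition of cluster 14, the removal of low-UMI cluster 13 and clusters fitted by themselves were added after the data were seen. The testing step was run on simulated class sums with 200 changed genes in each class. False genes were up to 20.2% of the calls in a class with gene-wise spread (cardiomyocyte-like cells). In endothelial-like cells 71.2% of genes changed 4-fold, 31.3% of genes changed 2-fold and none of the 67 genes changed 1.5-fold were recovered. Cell filtering, doublet calling, clustering and naming were not simulated. The simulated libraries varied independently, while in the real data deviations of same-numbered libraries correlated by 0.530 in endothelial-like cells. The rates may thus not hold for the real data.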

Results

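The data were UMI counts of single cells from ventricles of mouse embryos. They came from 2 libraries labelled het (Gata4fl/+) and 2 labelled KO (Gata4fl/fl), with Cre induced in the endothelium 3 days before collection. The libraries held 156491597 and 190207638 UMIs in het replicates 1 and 2, and 171252072 and 137890971 in KO replicates 1 and 2. Cells kept numbered 22581, 9937, 13727 and 6815 in het 1, het 2, KO 1 and KO 2, with medians of 4162, 14053, 7111 and 12302 UMIs per cell. Library het 1 stood apart: its lowest barcode held 1841 UMIs against 500 in het 2, 521 in KO 1 and 500 in KO 2. In het 1, 67.7% of cells (95% Wilson interval 67.0 to 68.3) fell in clusters that could not be named, against 6.83% (6.35 to 7.35) in het 2, 6.52% (6.12 to 6.95) in KO 1 and 3.17% (2.78 to 3.61) in KO 2. Clusters that mixed cardiomyocyte transcripts with those of other types held 14289 of the cells in het 1, and 180, 550 and 61 in het 2, KO 1 and KO 2. The Y-linked gene Ddx3y stood at 50.1, 76.1 and 44.8 CPM in endothelial-like cells of het 1, het 2 and KO 1; KO 2 had 0 UMIs, which allows up to 0.179 CPM. Xist, transcribed from the inactive X chromosome, stood at 779.9, 274, 787 and 1053 CPM in het 1, het 2, KO 1 and KO 2. Both transcripts were present in het 1, het 2 and KO 1, so these libraries held cells of both sexes, while KO 2 showed Xist only. The make-up by sex thus differed between libraries, and the tests did not adjust for it.

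The first comparison asked which cell types the ventricles held. Cardiomyocyte-like cells took 18.2% of the cells of het 1 (17.7 to 18.8), 41.2% of het 2 (40.3 to 42.2), 49.9% of KO 1 (49.1 to 50.7) and 53.3% of KO 2 (52.1 to 54.4). Their mean was 29.7% ± 16.2 (SD, n = 2) in het and 51.6% ± 2.38 in KO. Over named cells alone the means of cardiomyocyte-like cells were 50.3% ± 8.61 and 54.2% ± 1.15, a difference of 3.85 percentage points (exact permutation p = 1). Endothelial-like cells, made up of endocardial-like and vascular-like clusters and of low-UMI cluster 13, took 4.57% of het 1 (4.31 to 4.86), 11.7% of het 2 (11.1 to 12.4), 9.31% of KO 1 (8.84 to 9.81) and 10.9% of KO 2 (10.2 to 11.7). Their means were 8.15% ± 5.06 in het and 10.1% ± 1.13 in KO. Mesenchymal-like cells averaged 11.7% ± 11.2 in het and 13.5% ± 3.38 in KO, and epicardial-like cells 1.16% ± 1.13 and 2.26% ± 0.190. Erythroid-like cells averaged 10.2% ± 8.25 and 15.3% ± 3.32. Exact permutation tests gave p = 0.333 for cardiomyocyte-like and epicardial-like cells, the smallest p that 2 libraries against 2 allow. The difference for endothelial-like cells turned to −2.76 percentage points when shares were taken over named cells alone, and was −1.63 without het 1 and 5.53 without het 2; for mesenchymal-like cells it was −2.32 over named cells and −6.18 without het 1. Erythroid-like cells differed by −0.783 points without het 1.

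**Figure D1:**
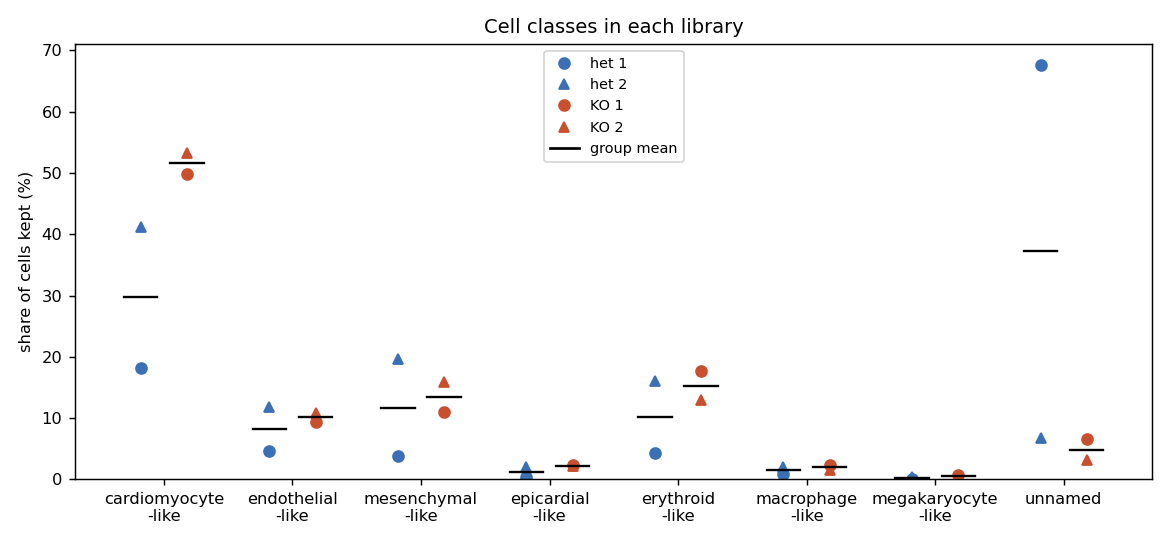
Share of the cells kept (%, vertical axis) that each cell class took in each library, with circles for replicate 1, triangles for replicate 2 and a black line for the mean of each group. Cardiomyocyte-like cells took 18.2% of het 1 and between 41.2% and 53.3% of the other libraries.

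Gata4, the zinc-finger transcription factor targeted here (ENSMUSG00000021944.15, chromosome 14, 63198922 to 63271692, minus strand, GRCm38), had more UMIs in endothelial-like cells of both libraries labelled KO. It stood at 84.6 and 82.4 CPM in het 1 and het 2 and at 157 and 159 CPM in KO 1 and KO 2, a mean of 83.5 ± 1.53 (SD, n = 2) against 158 ± 1.26 and a log2 difference of 0.92 (SE 0.129), from 831, 1814, 2662 and 2575 UMIs. In cluster 14, an unnamed group of cells with endothelial leading genes such as Ptprb and Klf2, Gata4 stood at 232 ± 15.1 CPM in het and 325 ± 9.65 in KO (log2 difference 0.48, SE 0.164, adjusted p = 0.999). Mesenchymal-like cells held 132 ± 13.2 and 132 ± 14.5 CPM, epicardial-like cells 93.5 ± 8.78 and 96.7 ± 10.3, and cardiomyocyte-like cells 63.0 ± 5.23 and 64.7 ± 1.07. Erythroid-like cells held 4.12 and 2.31 CPM and macrophage-like cells 3.46 and 5.59 CPM. Without TMM, erythroid-like cells held 2.96 CPM in het and 3.21 in KO, the other direction, since their TMM factors were 0.699 and 0.757 in het 1 and het 2 and 1.41 and 1.34 in KO 1 and KO 2. Over all genes, the adjusted p of Gata4 was 0.412 in endothelial-like cells and ranged from 4.02e-06 to 0.99997 over its alternatives. Adjusted over the list of cardiac and endothelial transcription factors alone it was 0.00764. Gata4 passed over all genes without KO 1 (log2 difference 0.94, adjusted p = 0.0342), and its log2 difference was 0.34 in the vascular-like cluster alone and 0.54 with cluster 14 added to the class. The UMIs were counted at the 3′ end of transcripts, and the labels do not say which exons were floxed, so the tag may lie outside the deleted part and its level checks neither the deletion nor the genotype.

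Neil2, a DNA glycosylase of base excision repair (ENSMUSG00000035121.6, chromosome 14, 63182443 to 63193856), lies on the same strand 5065 bp past the 3′ end of Gata4 and had the lowest p in endothelial-like cells. It stood at 11.7 ± 0.590 CPM in het and 50.3 ± 7.18 in KO there (SD, n = 2; log2 difference 2.10, SE 0.169). The log2 difference was 1.46 (SE 0.174) in cluster 14, 0.48 (SE 0.245) in mesenchymal-like, 0.08 (SE 0.475) in epicardial-like and 0.03 (SE 0.290) in cardiomyocyte-like cells. In macrophage-like cells it was 1.01 (SE 0.466), from 6, 8, 21 and 11 UMIs in het 1, het 2, KO 1 and KO 2, and in erythroid-like cells −0.85 (SE 0.562). The next gene past Neil2, Fdft1 of sterol synthesis, had 0.16 (SE 0.175) in endothelial-like cells, and Ctsb, a lysosomal protease on the other strand, had 0.19 (SE 0.150). The adjusted p of Neil2 was 0.136 in endothelial-like cells and 0.358 in cluster 14.

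**Figure D2:**
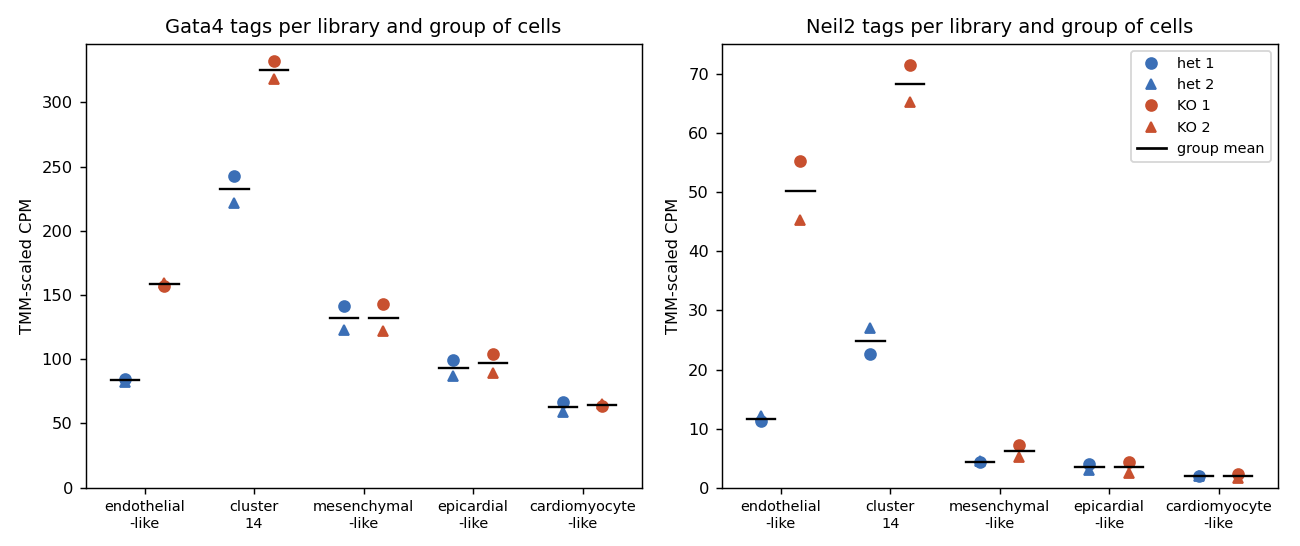
Levels of Gata4 and Neil2 (TMM-scaled CPM, vertical axis) in 5 groups of cells, with circles for replicate 1, triangles for replicate 2 and a black line for the mean of each group. In endothelial-like cells the means were 83.5 and 158 CPM for Gata4 and 11.7 and 50.3 CPM for Neil2, het and KO.

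**Figure D3:**
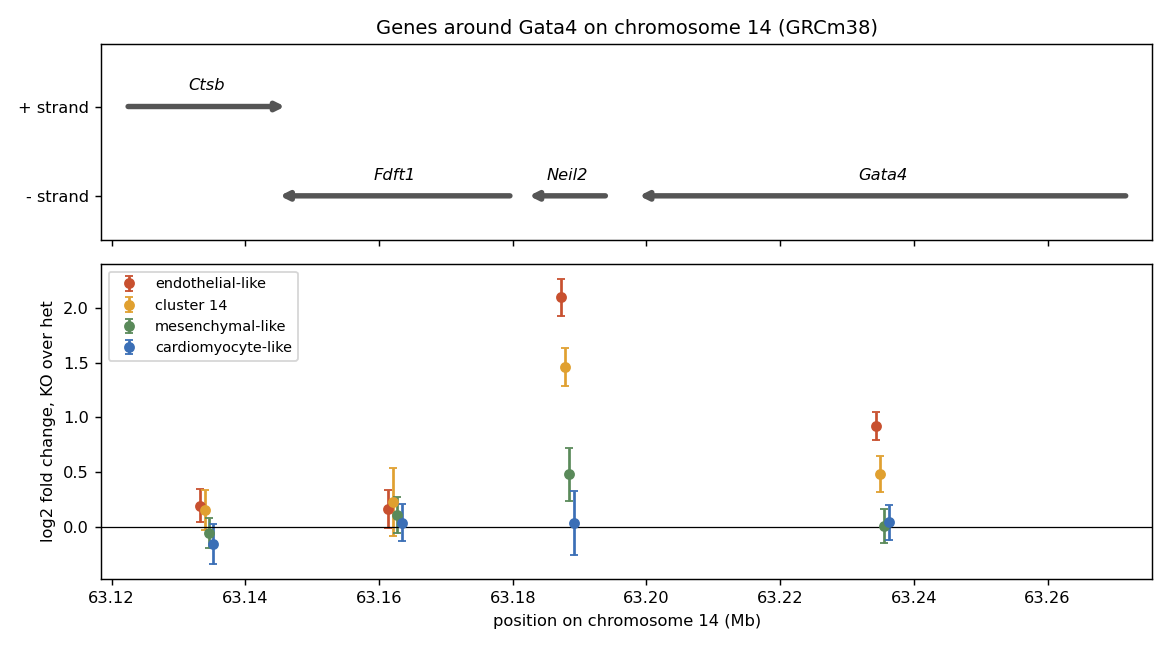
Genes on both strands around Gata4 on chromosome 14 (position in Mb) and, for each gene tested, the log2 fold change KO against het with its SE in 4 groups of cells. Neil2 had a log2 fold change of 2.10 in endothelial-like cells and Fdft1, the next gene on the strand, 0.16.

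Endothelial-like cells addressed the main question of the design, which genes differ between embryos with 2 and with 1 floxed Gata4 alleles when Cre is induced in the endothelium. The genes furthest apart included Vwf, the von Willebrand factor of endothelial storage granules (ENSMUSG00000001930.17, chromosome 6, 125546774 to 125686679), at 50.4 ± 8.73 CPM in het and 193 ± 20.0 in KO (SD, n = 2; log2 difference 1.94, SE 0.178). Fbln2, a matrix fibulin of the endocardial cushions (chromosome 6, 91212455 to 91272540), stood at 52.6 ± 1.90 and 136 ± 4.44 CPM (1.37, SE 0.131). Hapln1, which links hyaluronan to proteoglycans in the cardiac jelly, stood at 147 ± 4.31 and 288 ± 22.8 CPM (0.97, SE 0.149). Nfatc1, a transcription factor of the endocardium, stood at 82.4 ± 5.90 and 119 ± 2.41 CPM. Adjusted over the list of endocardial identity alone, these 4 rose, with adjusted p = 0.000247 for Vwf and Fbln2, 0.00254 for Hapln1 and 0.0256 for Nfatc1. Over all genes the adjusted p in edgeR was 0.136 for Vwf and Fbln2, 0.412 for Hapln1 and 0.950 for Nfatc1. Of 15 tested members, 11 were above 0, with a median log2 difference of 0.19 and a mean of 0.41. Camera gave adjusted p = 2.84e-05 for the list, and adjusted p = 0.681 with an estimated correlation. In the vascular-like cluster alone the median of this list was −0.10, and in the endocardial-like clusters alone it was 0.0364 (adjusted p = 0.0201).

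Genes of BMP and TGF-beta signalling formed the list with the lowest camera p among those that were higher: 21 of 26 tested members were above 0, with a median of 0.40 and adjusted p = 2.75e-09, and adjusted p = 0.591 with an estimated correlation. Adjusted over the list alone, 7 members rose. They included the ligand gene Bmp6 (chromosome 13, 38345107 to 38500302) at 10.6 ± 2.31 CPM in het and 39.4 ± 4.32 in KO (SD, n = 2; log2 difference 1.88, SE 0.200), and Acvrl1, an endothelial type I receptor, at 16.9 ± 0.478 and 37.1 ± 4.54 CPM. They also included the inhibitory Smads, with Smad6 at 63.1 ± 10.7 and 130 ± 2.99 and Smad7 at 146 ± 17.0 and 257 ± 5.80 CPM. Their adjusted p over the list alone was 0.00158 for Bmp6, 0.00382 for Acvrl1, 0.00438 for Smad6 and 0.0105 for Smad7. Over all genes it was 0.154 for Bmp6, 0.412 for Acvrl1 and Smad6 and 0.668 for Smad7 in edgeR.

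Among 35 cardiac and endothelial transcription factors, 25 were above 0 (median 0.17, camera adjusted p = 0.00839, and adjusted p = 0.681 with an estimated correlation). Adjusted over the list alone, 5 rose and 1 fell. Irx3, a homeobox gene of the conduction system and trabeculae (chromosome 8, 91798525 to 91802067), fell from 19.2 ± 0.758 to 9.25 ± 0.0347 CPM (SD, n = 2), a log2 difference of −1.05 (SE 0.157). Besides Gata4 and Nfatc1, the related factors Gata5 at 25.6 ± 0.0482 and 38.4 ± 3.94 CPM and Gata6 at 164 ± 0.946 and 247.5 ± 27.5 CPM rose. So did Isl1, a cardiac progenitor factor with few UMIs, at 0.187 ± 0.121 and 1.86 ± 0.870 CPM. Over all genes the adjusted p in edgeR was 0.412 for Irx3, 0.950 for Gata5 and Gata6 and 0.740 for Isl1. The list's adjusted p was 0.0591 without het 1 and 0.0541 without KO 2, and in the vascular-like cluster alone the log2 difference of Gata6 was −0.31.

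Flow-responsive genes had 9 of 13 members above 0 (median 0.18, camera adjusted p = 0.0368, and adjusted p = 0.741 with an estimated correlation). Adjusted over the list alone, 3 rose. Edn1, the endothelin ligand, stood at 19.3 ± 4.73 and 43.8 ± 6.29 CPM, Egr1, an immediate early factor, at 114 ± 19.1 and 202 ± 51.0 CPM, and the water channel gene Aqp1 at 11.6 ± 4.50 and 22.7 ± 1.04 CPM (SD, n = 2). Over all genes their adjusted p in edgeR was 0.613, 0.973 and 0.995. Aqp1 was also among the 10 leading genes of cluster 14, which this class leaves out. Whether cells like those of cluster 14 raised it here was not tested. The list did not pass without het 1 (0.168), KO 1 (0.173) or KO 2 (0.0935), in the endocardial-like clusters alone (0.401) or without low-UMI cluster 13 (0.0554), each an adjusted p. Genes of VEGF and sprouting had 16 of 20 members above 0 (median 0.14, adjusted p = 0.0206, and adjusted p = 0.767 with an estimated correlation). Of these, Unc5b, a netrin receptor gene of tip cells, rose over the list alone, at 24.6 and 44.6 CPM, and the receptor gene Flt1 stood at 389 and 533 CPM. Without KO 1 this list's adjusted p was 0.970 and its median 0.0030, with adjusted p = 0.0601 without het 1 and 0.13 without het 2. In the endocardial-like clusters alone its median was 0.0247 (adjusted p = 0.308), and without cluster 13 its adjusted p was 0.0658. The Notch pathway did not pass as a list (11 of 18 above 0, median 0.08, adjusted p = 0.159, and adjusted p = 0.767 with an estimated correlation). Its target Hey1 rose over the list alone, from 14.2 ± 1.62 to 30.6 ± 2.33 CPM, and Mfng, a modifier of Notch receptors, stood at 37.0 and 27.8 CPM. In the endocardial-like clusters alone the Notch list passed (median 0.17, adjusted p = 0.0175).

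Pan-endothelial genes had 13 of 17 members above 0 (median 0.08, camera adjusted p = 0.0118, and adjusted p = 0.767 with an estimated correlation). The receptor gene Eng stood at 576 and 862 CPM and Clec14a at 152 and 219 CPM. The list did not pass without het 1 (adjusted p = 0.563), KO 2 (0.380) or cluster 13 (0.0559), or in the endocardial-like clusters alone (median 0.0263, adjusted p = 0.242). Hypoxia and glycolysis had 18 of 25 above 0 (median 0.10, adjusted p = 0.0111, and adjusted p = 0.681 with an estimated correlation). The stress gene Ndrg1 stood at 17.8 and 27.7 CPM and Slc2a1, a glucose transporter gene, at 32.9 and 46.4 CPM. It did not pass without het 1 (adjusted p = 0.0511), het 2 (0.0756) or KO 1 (0.116), and its median was 0.44 in the endocardial-like clusters alone (adjusted p = 8.98e-10). Oxidative phosphorylation had all 29 tested members below 0 (median −0.18, adjusted p = 0.000118, and adjusted p = 0.767 with an estimated correlation), such as Cox5a of cytochrome oxidase at 456 and 359 CPM, and did not pass without het 2 (adjusted p = 0.0756) or KO 1 (0.546). In the endocardial-like clusters alone its median was −0.0058 (adjusted p = 0.928). Genes of cushion formation and endothelial-to-mesenchymal transition did not pass (11 of 19 above 0, median 0.04, adjusted p = 0.230, and adjusted p = 0.767 with an estimated correlation), and Snai1, a repressor of cell adhesion genes, stood at 3.71 and 6.35 CPM. Without het 1 that list's median was 0.38 (adjusted p = 0.0447), and it was −0.03 without het 2, −0.04 without KO 1 and 0.30 in the endocardial-like clusters alone (adjusted p = 0.00464).

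Transcripts of other cell types also differed between the groups in endothelial-like cells. All 16 tested cardiomyocyte transcripts were below 0 (median −1.06, camera adjusted p = 4.01e-07, and adjusted p = 0.767 with an estimated correlation), as were all 22 sarcomere genes (median −1.06, adjusted p = 6.59e-10, and adjusted p = 0.767 with an estimated correlation). The troponin gene Tnni1 stood at 287, 137, 121 and 85.0 CPM and the myosin light chain gene Myl4 at 399, 160, 156 and 89.7 CPM in het 1, het 2, KO 1 and KO 2. Cardiomyocyte transcripts took 0.601% of UMIs in het 1 (95% Wilson interval 0.596 to 0.606), 0.230% in het 2 (0.228 to 0.232), 0.291% in KO 1 (0.289 to 0.294) and 0.110% in KO 2 (0.109 to 0.112). In the endocardial-like clusters alone KO 1 was highest, and the group means were 0.179% in het and 0.172% in KO. In those clusters neither list passed, with medians of −0.0480 for cardiomyocyte transcripts (adjusted p = 0.393) and −0.0674 for sarcomere genes (0.160). Without het 1 the median of that list was −0.25 and that of the sarcomere list −0.29. Mesenchymal transcripts had 7 of 12 above 0 (median 0.15, adjusted p = 0.0236, and adjusted p = 0.767 with an estimated correlation). Among them Cthrc1, a secreted matrix protein gene, rose over the list alone, from 7.32 ± 2.57 to 26.6 ± 6.22 CPM (SD, n = 2). This list's median was 0.62 without het 1, −0.14 without het 2, −0.45 in the vascular-like cluster alone and 0.61 in the endocardial-like clusters alone (adjusted p = 1.02e-08); it also did not pass without KO 1 (adjusted p = 0.173) or KO 2 (0.0541). The vascular-like cluster 22 held 284 of the 1033 endothelial-like cells of het 1, 150 of 1166 in het 2, 158 of 1278 in KO 1 and 78 of 743 in KO 2.

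No gene passed over all 15236 genes in edgeR, where the lowest adjusted p was 0.136 and 546 genes had an unadjusted p under 0.05. With the replicate number as a block, whose meaning the labels do not give, edgeR called 559 genes, 286 higher and 273 lower in KO. DESeq2 called 27 genes, 24 higher and 3 lower in KO, and limma-voom called 0. The 3 lower ones were Ptpre, a phosphatase gene (57.9 ± 12.9 and 25.7 ± 0.980 CPM), Rasgrp2, an exchange factor gene of Rap (47.1 ± 0.919 and 20.9 ± 4.25 CPM), and the smooth muscle actin gene Acta2 (SD, n = 2). Ptpre had a log2 difference of 0.06 in the vascular-like cluster alone. The 24 higher ones included Neil2, Vwf, Fbln2, Bmp6 and Gata4. Another was Dkk1, a secreted inhibitor of Wnt signalling (chromosome 19, 30545863 to 30549665), at 0.114 ± 0.161 CPM in het and 8.33 ± 0.763 in KO, from 0, 5, 150 and 126 UMIs in het 1, het 2, KO 1 and KO 2. Its adjusted p in edgeR was 0.136, and with cluster 14 added its log2 difference was 2.63. Also among them were Emb, an adhesion molecule gene (11.9 ± 0.542 and 32.3 ± 1.59 CPM), the fibrillin gene Fbn2 (74.1 ± 1.57 and 163.5 ± 20.997 CPM) and Thsd7a (15.7 and 33.9 CPM). Col13a1, a transmembrane collagen gene, stood at 99.9 ± 4.29 and 60.7 ± 0.525 CPM and the peptidase gene Dpp4 at 98.8 ± 9.98 and 58.8 ± 8.79 CPM. Counts in edgeR were 9 without het 1, 9 without het 2, 92 without KO 1 (36 higher and 56 lower) and 4 without KO 2 (Neil2, Vwf, Dkk1 and Hemgn), and 238 with no count filter (100 higher and 138 lower). Fitted by itself, endocardial-like cluster 11 gave 3 calls in edgeR, Dkk1, Vwf and Ptpre. Both endocardial-like clusters together gave 0 (672 at an unadjusted p under 0.05), as did cluster 13 (114) and vascular-like cluster 22 (669), and no other tool was run on single clusters. In 27.8% of genes the libraries of the groups did not overlap, against 33.3% by chance, with 2219 genes higher and 2018 lower in KO.

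**Figure D4:**
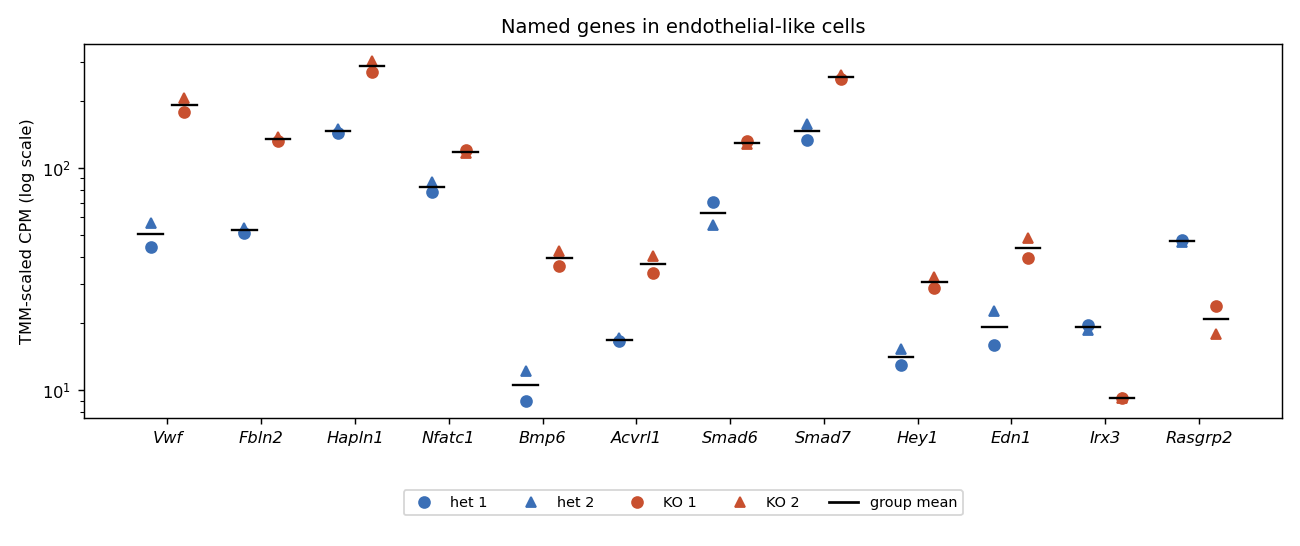
Levels of 12 genes in endothelial-like cells (TMM-scaled CPM, log axis), with circles for replicate 1, triangles for replicate 2 and a black line for the mean of each group. Vwf stood at 50.4 CPM in het and 193 CPM in KO, and Irx3 at 19.2 and 9.25 CPM.

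Cardiomyocyte-like cells, which the endothelial Cre driver does not target, were compared to ask what differs in the myocardium. The natriuretic peptide genes were higher in KO without passing. Nppb stood at 87.7 ± 58.2 CPM in het and 167 ± 21.4 in KO (SD, n = 2; log2 difference 0.93, SE 0.363) and Nppa had a log2 difference of 0.39 (SE 0.201). Bmp10, a ligand of trabecular growth, stood at 14.7 ± 4.43 and 20.9 ± 3.52 CPM. With them, the trabecular list had 8 of 13 members above 0 (median 0.12, camera adjusted p = 0.0659, and adjusted p = 0.742 with an estimated correlation), and passed without het 1 (adjusted p = 0.0308) and without KO 2 (0.0323). Compact myocardium had 5 of 9 above 0, a median of 0.01, a mean of −0.07 and a test directed down (adjusted p = 0.704), with Prdm16, a regulator of compact myocardium, at 16.3 and 14.2 CPM. Growth factor receptors of the myocardium had all 15 members below 0 (median −0.22, adjusted p = 0.000983, and adjusted p = 0.742 with an estimated correlation). Among them were the Wnt receptor gene Fzd2 at 56.9 ± 13.97 and 42.1 ± 5.67 CPM and Notch2 at 7.91 and 5.37 CPM. Cardiac jelly and its proteases had 16 of 17 members below 0 (median −0.23, adjusted p = 0.000983, and adjusted p = 0.742 with an estimated correlation). The protease gene Mmp14 stood at 12.8 and 8.72 CPM and the fibronectin gene Fn1 at 78.3 and 57.8 CPM. Neither of these lists passed without het 1 (adjusted p = 0.0645 for receptors and 0.136 for cardiac jelly) or without KO 2 (0.704 and 0.492).

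Hypoxia and glycolysis in these cells had 21 of 25 members above 0 (median 0.17, camera adjusted p = 0.000983, and adjusted p = 0.742 with an estimated correlation). Bnip3, a mitophagy gene, stood at 259 ± 18.5 and 359 ± 17.3 CPM (SD, n = 2). Oxidative phosphorylation had 27 of 30 above 0 (median 0.14, adjusted p = 0.00223, and adjusted p = 0.750 with an estimated correlation). Cox7a1 stood at 206 ± 31.5 and 299 ± 69.4 CPM. G1/S genes had 22 of 25 above 0 (median 0.12, adjusted p = 0.0297, and adjusted p = 0.750 with an estimated correlation). The cyclin gene Ccne1 stood at 23.6 and 29.0 CPM and Pcna, the replication clamp gene, at 136 ± 26.6 and 168 ± 4.49 CPM. Hypoxia, oxidative phosphorylation and G1/S did not pass without het 1 (adjusted p = 0.808, 0.560 and 0.545) or without KO 2 (0.688, 0.770 and 0.770), where the medians of oxidative phosphorylation and G1/S were −0.07 and −0.07. Markers of other cells moved beside these lists: all 17 pan-endothelial genes (median −0.58, adjusted p = 0.00151) and all 12 mesenchymal transcripts (median −0.38, adjusted p = 0.00219) were below 0, each with adjusted p = 0.742 with an estimated correlation. Without het 1 these medians were 0.19 and 0.04 (adjusted p = 0.733 and 0.863), and neither list passed without KO 2 (0.868 and 0.704). Of the cardiomyocyte-like cells of het 1, 2009 of 4120 lay in cluster 10 and 1019 in cluster 16, while cluster 10 held 6 of the 4096 such cells of het 2, 3 of the 6848 of KO 1 and none of KO 2. Other clusters of this class also differed between the libraries. Cluster 0, whose leading genes include Mb and Cox7a1, took 5.68%, 23.5%, 38.6% and 33.6% of the class in het 1, het 2, KO 1 and KO 2. Cluster 9, led by the sarcomere gene Ttn, took 10.2%, 26.5%, 10.8% and 9.34%, with only het 2 apart. It supplied 9655350 of the 30583987 UMIs of the class in het 1, 41057439 of 58987111 in het 2, 17099477 of 43931106 in KO 1 and 15650991 of 40135256 in KO 2. The values above are for the whole class and include these shifts.

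In these cells 13 lists passed camera, 3 up and 10 down, against 1 without het 1, 19 without het 2, 22 without KO 1 and 2 without KO 2, and 0 with an estimated correlation or in fry. No gene passed in edgeR over 16409 genes (lowest adjusted p 0.9997, 253 at an unadjusted p under 0.05), and DESeq2 and limma-voom called 0. Without het 1 edgeR called 61, without het 2 25, without KO 1 58 and without KO 2 7, and 34 with no count filter. Of 7 clusters fitted by themselves, cluster 16 gave 1 call in edgeR, the cardiac long noncoding RNA Mhrt, and the others gave 0, with between 116 and 360 genes at an unadjusted p under 0.05; no other tool was run on them. Among genes with the lowest p were the metallothionein gene Mt3 at 25.9 ± 1.39 and 44.7 ± 15.2 CPM (SD, n = 2), the histone gene H3c2 at 16.7 and 29.4 CPM and the microfibril gene Mfap2 at 26.8 ± 1.13 and 18.4 ± 0.687 CPM.

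Mesenchymal-like cells had higher hypoxia and glycolysis genes in KO: 22 of 25 were above 0 (median 0.16, camera adjusted p = 6.86e-05, and adjusted p = 0.988 with an estimated correlation). Vegfa, the vascular growth factor gene, stood at 41.4 ± 1.31 CPM in het and 56.4 ± 6.37 in KO (SD, n = 2; log2 difference 0.45, SE 0.140) and Bnip3 at 69.7 ± 1.05 and 89.5 ± 1.37 CPM. The list did not pass without het 1 (adjusted p = 0.368) or without KO 2 (0.608). Cushion and transition genes had 14 of 22 above 0, a median of 0.05, a mean of −0.03 and a test directed down (adjusted p = 0.983). Msx2, a homeobox gene of the cushions, stood at 4.14 and 2.49 CPM and the ligand gene Bmp2 at 56.9 ± 1.69 and 47.1 ± 1.38 CPM. Markers of other cells were lower: all 11 macrophage transcripts were below 0 (median −1.04, adjusted p = 1.88e-05, and adjusted p = 0.988 with an estimated correlation). The lysozyme gene Lyz2 stood at 3.14 and 1.39 CPM and the complement gene C1qc at 2.64 and 1.15 CPM. Of the cardiomyocyte transcripts, 15 of 16 were below 0 (median −0.42, adjusted p = 0.0128, and adjusted p = 0.988 with an estimated correlation), with Tnni1 at 144 ± 43.9 and 101 ± 19.5 CPM. Without het 1 the medians were −0.20 for macrophage and 0.44 for cardiomyocyte transcripts, and without KO 2 they were −0.58 and 0.03.

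In mesenchymal-like cells no gene passed in edgeR over 16896 genes (lowest adjusted p 0.99998, 168 at an unadjusted p under 0.05); DESeq2 called 1 and limma-voom 0. The DESeq2 gene was the chemokine gene Cxcl12 (chromosome 6, 117168535 to 117181367), at 24.9 ± 5.78 CPM in het and 11.3 ± 0.203 in KO (SD, n = 2; log2 difference −1.15, SE 0.192). Tnxb, a tenascin gene, stood at 28.2 ± 1.69 and 41.3 ± 5.35 CPM. In edgeR 11 genes passed without het 1, 10 without het 2, 14 without KO 1 and 9 without KO 2, and 37 with no count filter. Fitted by itself, cluster 19 gave 1 call in edgeR, the carbonic anhydrase gene Car3, and clusters 8 and 12 gave 0, with 233 and 120 genes at an unadjusted p under 0.05; no other tool was run on them.

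Epicardial-like cells, the outer layer of the heart and the smallest class tested with 81, 194, 329 and 145 cells in het 1, het 2, KO 1 and KO 2, had all 28 G2/M genes above 0 (median 0.41, camera adjusted p = 8.73e-12, and adjusted p = 0.893 with an estimated correlation). The proliferation marker Mki67 stood at 131 ± 29.7 CPM in het and 237 ± 80.1 in KO (SD, n = 2; log2 difference 0.85, SE 0.267) and the topoisomerase gene Top2a at 135 ± 55.1 and 233 ± 69.1 CPM. Hypoxia and glycolysis had 23 of 24 above 0 (median 0.31, adjusted p = 8.42e-08, and adjusted p = 0.893 with an estimated correlation). Bnip3 stood at 75.8 ± 29.1 and 126 ± 1.56 CPM and Vegfa at 81.7 ± 2.46 and 122 ± 37.8 CPM. Without het 1 the medians of both lists were 0.10 and 0.09 and neither passed (adjusted p = 0.623 and 0.477). Cardiomyocyte transcripts had 15 of 16 below 0 (median −0.51, adjusted p = 1.22e-05, and adjusted p = 0.893 with an estimated correlation) and mesenchymal transcripts 9 of 12 (median −0.22, adjusted p = 0.0234, and adjusted p = 0.893 with an estimated correlation). The first did not pass without het 2 (adjusted p = 0.120) or KO 2 (0.823), the second without het 1 (0.399) or KO 1 (0.521). Cthrc1 stood at 8.73 ± 5.11 and 2.93 ± 0.996 CPM, and the matrix gene Postn at 79.4 CPM in het 1 and 17.2, 15.2 and 18.0 CPM in het 2, KO 1 and KO 2.

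The growth factor gene Igf1 fell when adjusted over the list of signals to the myocardium alone (adjusted p = 0.0429), from 51.5 ± 20.0 to 23.8 ± 2.06 CPM (SD, n = 2) in epicardial-like cells. The proteoglycan gene Vcan fell over the cushion list alone (adjusted p = 0.0481) and stood at 191, 40.4, 31.9 and 25.0 CPM in het 1, het 2, KO 1 and KO 2. Over all genes the adjusted p in edgeR was 0.99994 for Igf1 and for Vcan. The histone gene H3c3 stood at 45.2 ± 0.246 and 107 ± 3.66 CPM (log2 difference 1.25, SE 0.179). No gene passed in edgeR over 13928 genes (lowest adjusted p 0.572, 232 at an unadjusted p under 0.05), limma-voom called 0, and DESeq2 called 3: H3c3 and the globin genes Hbb-bt and Hbb-bs. In edgeR 33 passed without het 1, 78 without het 2, 35 without KO 1 and 15 without KO 2, and 21 with no count filter.

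Erythroid-like and macrophage-like cells were tested as other classes. The erythroid-like clusters differed between the groups: cluster 1, led by the embryonic globin genes Hbb-bh1, Hba-x and Hbb-y, held 923 of 991 such cells in het 1, 1409 of 1596 in het 2, 1489 of 2420 in KO 1 and 476 of 881 in KO 2. The libraries of the groups did not overlap in 53.6% of genes in erythroid-like cells, against 33.3% by chance. In edgeR no gene passed in either class, with 1746 of 12625 genes at an unadjusted p under 0.05 in erythroid-like and 224 of 11853 in macrophage-like cells. DESeq2 called 300 and 7 genes and limma-voom called 0 in both. Counts without het 1, het 2, KO 1 and KO 2 were 93, 2444, 15 and 6 in erythroid-like cells and 27, 4, 73 and 100 in macrophage-like cells, where the 4 were Rsad2, Mmp12, Gm43305 and Rhox5.

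The last comparison tested whether the difference between groups was itself different in endothelial-like and cardiomyocyte-like cells. For Neil2 the log2 difference in endothelial-like cells exceeded that in cardiomyocyte-like cells by 2.03 (SE 0.201), and for Gata4 by 0.85 (SE 0.148). Edn1 (1.504, SE 0.204), the basement membrane collagen gene Col4a6 (1.55, SE 0.226), Unc5b (0.98, SE 0.160) and Fbn2 (1.26, SE 0.213) followed. On the other side stood Irx3 (−1.42, SE 0.201), Nxpe2 (−3.28, SE 0.570), Rasgrp2 (−1.42, SE 0.249), the taurine synthesis gene Cdo1 (−1.55, SE 0.286) and Smim1 (−0.80, SE 0.153). Nxpe2 was not lower in KO endothelial-like cells (log2 difference 0.33). It stood there at 3.16, 1.73, 5.14 and 0.803 CPM in het 1, het 2, KO 1 and KO 2. In cardiomyocyte-like cells it had too few counts to be tested, so its value here rests on those few counts. None passed over 17387 genes in edgeR, the only tool run for this comparison: the lowest adjusted p was 0.175, for Neil2, and 1047 genes had an unadjusted p under 0.05. The count was 0 without het 1, 0 without het 2, 151 without KO 1 and 16 without KO 2, and 264 with no count filter.

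**Figure D5:**
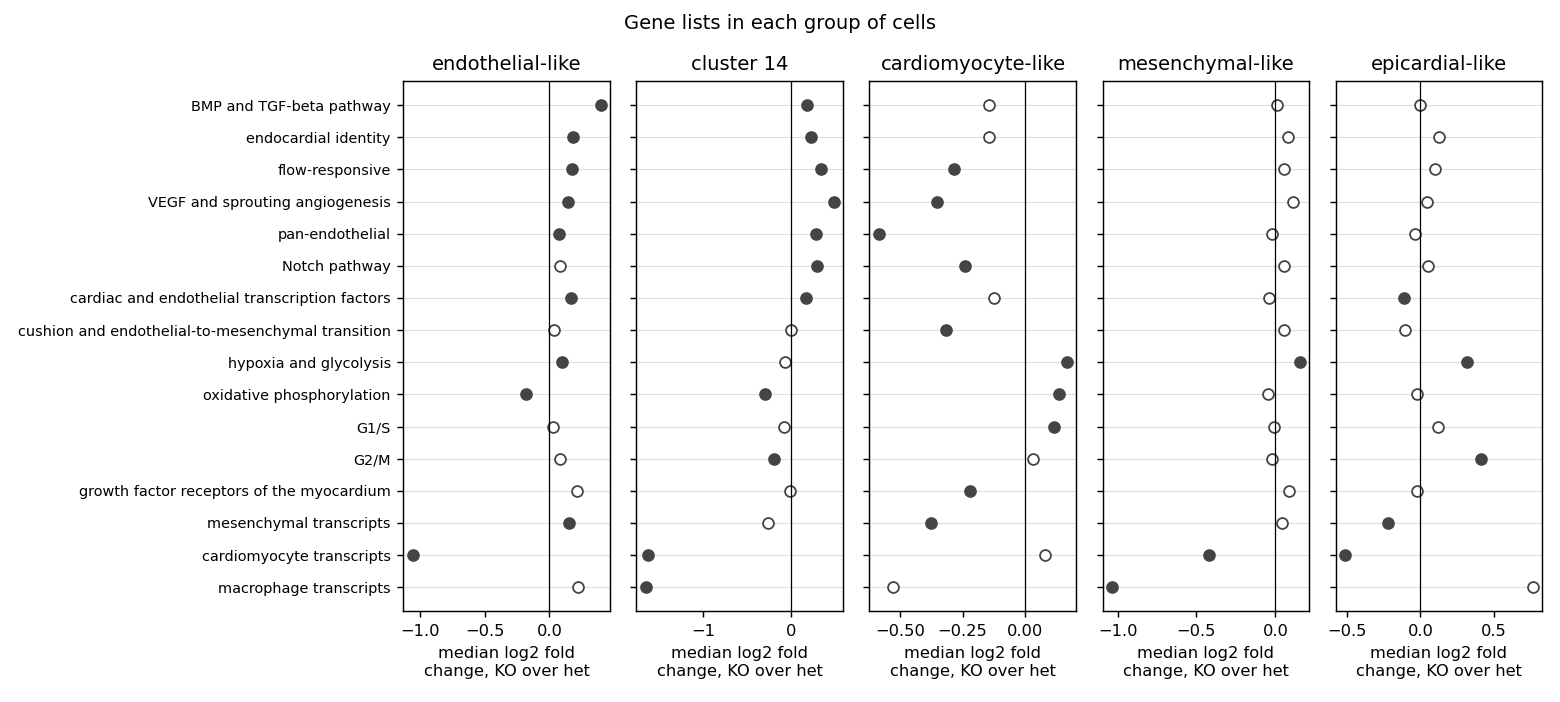
Median log2 fold change KO against het (horizontal axis) of gene lists in 5 groups of cells, with filled points where the camera adjusted p was under 0.05. In endothelial-like cells the BMP and TGF-beta pathway had a median of 0.40 and cardiomyocyte transcripts −1.06, and no list passed with an estimated correlation.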

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

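No tests were run in this part: a fixed rule on sequences outside the comparisons picked out 1 value, and no explanation of it was weighed. FloxGata4_ctrl, a sequence that the submitters added to the reference and whose content the labels do not give, stood out because its mean in endothelial-like cells of KO lay above both het libraries, a signal in a feature that the comparisons did not use. That mean was 3.03 ± 1.41 CPM in KO and 1.37 ± 0.263 in het (SD, n = 2), from 15, 27, 65 and 34 UMIs in het 1, het 2, KO 1 and KO 2. By library it stood at 1.56, 1.18, 4.02 and 2.03 CPM. In cardiomyocyte-like cells, het 1 and KO 1 held 2.26 and 2.66 CPM and het 2 and KO 2 held 0.678 and 0.947 CPM. The companion sequence FloxGata4 had 0 UMIs in endothelial-like cells of every library, which allows up to 0.311 CPM in het 1, the library with the fewest UMIs in that class, and 3, 0, 1 and 1 UMIs in cardiomyocyte-like cells.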

How the results depend on the processing

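The tests in cluster 14, those on cells of at least 5000 UMIs, on named cells only, with cluster 14 added and without cluster 13, and the alternatives for erythroid-like and macrophage-like cells were chosen after results were seen. Direction held for named genes in 1356 of 1359 alternatives, for lists in 557 of 579, for shares in 79 of 88, for Gata4 in 100 of 106 and for the interaction in 104 of 104. Most named genes and most interaction genes were picked for a low p in the same libraries that the alternatives reuse. For most named genes both KO libraries lay on one side of both het libraries. Leaving out a library or changing the tool could then hardly turn the direction. The counts for named genes and the interaction are thus no independent check. For gene counts, 47 of 106 alternatives gave more calls and 59 also gave 0. The cause was not tested for any change below unless stated. Some genes had too few counts to be tested in the vascular-like cluster or at another resolution. Depth limits the genes with few UMIs, such as Isl1. The epicardial-like class held 1908823 UMIs in het 1 against 7456038, 9179570 and 6899454 in het 2, KO 1 and KO 2. In simulated data with gene-wise spread, 32.8% of genes changed 2-fold and 81.8% of genes changed 4-fold were recovered in that class. The shares were 31.3% and 71.2% in endothelial-like cells. The simulated libraries varied independently, without a deviation shared by same-numbered libraries, so these shares may not hold for the real data.

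DESeq2 called 27 genes in endothelial-like, 1 in mesenchymal-like, 3 in epicardial-like, 28 in cluster 14, 300 in erythroid-like and 7 in macrophage-like cells, where edgeR called 0. With DESeq2 statistics Gata4 in endothelial-like cells passed at 0.91 (adjusted p = 0.00037), and 19, 22, 10 and 14 lists passed in endothelial-like, cardiomyocyte-like, mesenchymal-like and epicardial-like cells, against 11, 13, 5 and 6. With no count filter edgeR called 238 genes in endothelial-like, 34 in cardiomyocyte-like, 37 in mesenchymal-like, 21 in epicardial-like, 256 in cluster 14, 480 in erythroid-like and 98 in macrophage-like cells, and 264 for the interaction. Of the 238, 230 were genes that the filter keeps. Without the filter Gata4 was at 0.92 in endothelial-like cells (adjusted p = 0.000384, in a range from 4.02e-06 to 0.99997 over its alternatives) and turned to −0.0028 in mesenchymal-like cells.

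Replicates share only their numbers across the groups, so the replicate number was tried as a block. With the block edgeR called 559 genes (286 higher and 273 lower) in endothelial-like, 68 in cardiomyocyte-like, 3 in mesenchymal-like (Cxcl12, Fam124a and Acan, named after their values were seen), 51 in epicardial-like, 43 in cluster 14, 3538 in erythroid-like and 6 in macrophage-like cells. Gata4 was at 0.92 in endothelial-like (adjusted p = 4.02e-06) and −0.85 in erythroid-like cells, 20 lists passed in cardiomyocyte-like cells, and the median of the cushion list in mesenchymal-like cells was 0.0495, where its test turned. Deviations of same-numbered libraries from their group means correlated across genes, by 0.530 in endothelial-like, 0.485 in cardiomyocyte-like, 0.490 in mesenchymal-like, 0.352 in epicardial-like, 0.394 in cluster 14, 0.548 in erythroid-like and 0.438 in macrophage-like cells. In endothelial-like cells log CPM correlated by 0.9857 between het 1 and KO 1 and by 0.9857 between het 2 and KO 2. The other pairs there ranged from 0.9722 to 0.9812. In erythroid-like cells the KO libraries were the closest pair (0.9737). A difference between replicate numbers adds to the spread in the test without a block. Genes are not independent replicates, and nothing in the labels says what a number stands for.

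With a correlation estimated per list 0, 0, 0, 0 and 0 lists passed in endothelial-like, cardiomyocyte-like, mesenchymal-like and epicardial-like cells and cluster 14, and fry also gave 0 in each. With limma-voom 17 lists passed in endothelial-like cells. At a resolution of 0.5, 20 passed in endothelial-like and 20 in cardiomyocyte-like cells, and the compact myocardium list in the latter was at 0.0631. With doublets kept 3 passed in mesenchymal-like cells. At equal depth the cushion list in mesenchymal-like cells was at 0.0458 with its test turned. With cells of at least 5000 UMIs the interaction had 8 genes. With cluster 14 added, the mesenchymal list in endothelial-like cells was at −0.22. In the vascular-like cluster alone the log2 difference of Cthrc1 in endothelial-like cells was −0.000408, of Gata6 in endothelial-like cells −0.31 and of Ptpre in endothelial-like cells 0.0615. List medians there were at −0.10 for endocardial identity, 0.0207 for transcription factors with the test turned, −0.45 for mesenchymal transcripts and −0.23 for cushion genes. Over named cells only, shares differed by −2.76 points for endothelial-like, −0.349 for macrophage-like and −2.32 for mesenchymal-like cells.

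Leaving out each library in turn leaves a group with 1 library, assumed to vary like the other group. Counts of genes ranged from 4 to 92 in endothelial-like, 7 to 61 in cardiomyocyte-like, 9 to 14 in mesenchymal-like, 15 to 78 in epicardial-like, 0 to 160 in cluster 14, 6 to 2444 in erythroid-like and 4 to 100 in macrophage-like cells, and 0 to 151 for the interaction. Gata4 ranged from 0.91 to 0.94 in endothelial-like, −0.0395 to 0.12 in cardiomyocyte-like, −0.11 to 0.12 in mesenchymal-like, −0.0546 to 0.16 in epicardial-like, 0.42 to 0.56 in cluster 14, −1.49 to −0.22 in erythroid-like and 0.48 to 0.96 in macrophage-like cells. Lists passing ranged from 11 to 15 in endothelial-like, 1 to 22 in cardiomyocyte-like, 1 to 9 in mesenchymal-like, 3 to 9 in epicardial-like cells and 10 to 21 in cluster 14. Differences in share ranged, in points, from 10.3 to 33.3 for cardiomyocyte-like, −1.63 to 5.53 for endothelial-like, 0.310 to 1.90 for epicardial-like, −0.783 to 10.9 for erythroid-like, −0.147 to 1.12 for macrophage-like, −0.0139 to 0.472 for megakaryocyte-like and −6.18 to 9.65 for mesenchymal-like cells. Medians of lists that turned ranged in endothelial-like cells from 0.0030 to 0.32 for VEGF, −0.14 to 0.62 for mesenchymal transcripts and −0.0378 to 0.38 for cushion genes. In cardiomyocyte-like cells they ranged from −0.0662 to 0.29 for oxidative phosphorylation, −0.0659 to 0.27 for G1/S, −0.10 to 0.0347 for compact myocardium, −1.13 to 0.19 for pan-endothelial genes and −0.89 to 0.0351 for mesenchymal transcripts. In mesenchymal-like cells cardiomyocyte transcripts ranged from −1.10 to 0.44 and cushion genes from −0.0386 to 0.11, and in cluster 14 cardiomyocyte transcripts ranged from −2.36 to −0.0014.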

Other observations

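The comparison in cluster 14 was added after the clusters were seen, and the tests of strain variants, of RNA from other Gata4-expressing cells, of genotype for Neil2 and of free RNA were chosen after their results were seen. Cluster 14 held cells with endothelial leading genes (Ptprb, Gja4, Klf2, Wnt4, Wnt9b) that carried EGFP at 1990 CPM, with the fixed endothelial markers raised but none of them among its 10 leading genes, and with 729, 409, 258 and 117 cells in het 1, het 2, KO 1 and KO 2. Endothelial-like cells numbered 1033, 1166, 1278 and 743 in the same libraries, so cluster 14 was smaller beside them in both KO libraries. At a resolution of 2, clusters 25 and 31 shared its leading genes Wnt4, Aqp1 and Klf2. Doublets included, cluster 25 held 312, 299, 247 and 108 cells in het 1, het 2, KO 1 and KO 2. Cluster 31, with 2.51% of UMIs from cardiomyocyte markers, held 544, 115, 19 and 9. Barcodes mixed with cardiomyocyte transcripts may thus make up part of cluster 14, above all in het 1. The log2 differences of Gata4 and Dkk1 in the endothelial-like class were smaller with cluster 14 added. Of the leading genes of cluster 14, Aqp1 and Cyp26b1 were higher in that class in KO (Cyp26b1 by 1.75 in DESeq2). The others were not compared as a set. Whether like cells fell in the class in KO and in cluster 14 in het was not tested. Flow-responsive genes were higher there in KO, with 13 of 14 members above 0 (median 0.33, camera adjusted p = 1.28e-06, and adjusted p = 0.413 with an estimated correlation). Adjusted over the list alone 4 rose, among them Thbd, the endothelial anticoagulant receptor gene, from 48.8 ± 3.91 to 106 ± 7.76 CPM (SD, n = 2), and the flow-induced factor Klf4, from 258 ± 9.99 to 434 ± 92.4 CPM. Genes of VEGF and sprouting had 13 of 17 above 0 (median 0.49, adjusted p = 2.91e-06, and adjusted p = 0.413 with an estimated correlation), of which Vegfa rose over the list alone from 42.8 ± 2.55 to 88.7 ± 5.87 CPM and its co-receptor gene Nrp2 from 82.9 ± 1.89 to 155 ± 0.265 CPM. The BMP and TGF-beta pathway had 20 of 26 above 0 (median 0.18, adjusted p = 0.00234, and adjusted p = 0.413 with an estimated correlation), and 3 members rose over the list alone: Acvrl1 from 5.07 ± 0.941 to 22.2 ± 9.49 CPM, Bmp2 from 12.6 ± 2.79 to 53.1 ± 30.6 CPM and Tgfb2 from 135 ± 1.97 to 246 ± 45.8 CPM. Without KO 1 that list did not pass (adjusted p = 0.0834). Signals to the myocardium had 15 of 17 above 0 (median 0.51, adjusted p = 0.00165, and adjusted p = 0.413 with an estimated correlation).

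Genes of cluster 14 with the lowest p were Slc6a6, a taurine transporter gene, at 48.9 ± 1.77 CPM in het and 185 ± 35.6 in KO (SD, n = 2; log2 difference 1.92, SE 0.191), and Sema3g, a semaphorin gene of arteries, at 5.24 ± 0.457 and 26.0 ± 1.13 CPM (2.31, SE 0.219), each with an adjusted p of 0.173 over all genes. Fbln5, an elastic fibre gene, stood at 62.1 ± 10.4 and 24.2 ± 10.2 CPM. Transcripts of other cells were lower: cardiomyocyte transcripts had 15 of 16 below 0 (median −1.63, adjusted p = 1.26e-05, and adjusted p = 0.534 with an estimated correlation), with the sarcomere gene Tcap at 35.6, 13.1, 3.36 and 3.98 CPM in het 1, het 2, KO 1 and KO 2, and erythroid transcripts had all 10 below 0 (median −1.40, adjusted p = 1.28e-06, and adjusted p = 0.487 with an estimated correlation). Cardiomyocyte transcripts took 1.06% of UMIs in het 1 (95% Wilson interval 1.056 to 1.07), 0.202% in het 2 (0.1997 to 0.205), 0.210% in KO 1 (0.206 to 0.214) and 0.198% in KO 2 (0.194 to 0.203). Without het 1 their median was −0.0014. In edgeR 0 of 13013 genes passed, with 514 at an unadjusted p under 0.05; DESeq2 called 28 and limma-voom 0. EdgeR counts were 21 without het 1, 160 without het 2, 9 without KO 1 and 0 without KO 2.

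Gata4 and Neil2 tags were both higher in KO endothelial-like cells. A strain variant carried with the floxed allele that acts alike in every cell would raise Neil2 everywhere, but the median log2 difference of the 5 tested classes outside the endothelium was 0.0850, and in 4 of them the upper bound was at most 1.03 (in epicardial-like cells), against a lower bound of 1.76 in endothelial-like cells. RNA from other Gata4-expressing cells would also reach cells that lack Gata4, but without TMM the highest Gata4 level of a library in macrophage-like and erythroid-like cells was 5.93 CPM (highest upper bound 7.94), against 67.6 CPM between the closest het and KO libraries of endothelial-like cells, and at equal cell number and depth Gata4 was at 1.05 and Neil2 at 2.07, which argues against depth. Still open is that transcripts of the recombined Gata4 allele may run on into the next gene. The ratio of Neil2 in endothelial-like cells with a Gata4 UMI to that in cells without one was taken within clusters. It was 1.597 (95% bootstrap interval 1.14 to 2.39) in KO 1 and 3.49 (2.08 to 6.91) in KO 2. It was 1.66 (1.18 to 2.60) in het 2 and 1.01 (0.593 to 1.74) in het 1. Het embryos also carried 1 floxed allele and the induced Cre, so these ratios cannot tell run-on apart from other explanations. Genotype as such stays open too, since Neil2 was higher by 1.46 in cluster 14, the other group with an endothelial profile. A strain variant that acts in some cell types only cannot be told apart from it. In macrophage-like cells Neil2 was at 1.01 (SE 0.466, upper bound 1.94) from 6, 8, 21 and 11 UMIs in het 1, het 2, KO 1 and KO 2. EGFP stood at 215 CPM in macrophage-like cluster 20 and at 480 and 554 CPM in mesenchymal-like clusters 8 and 19. In cardiomyocyte-like clusters 9 and 16 it stood at 68.4 and 242 CPM. Whether cells of these classes had recombined was not tested, so a rise of Neil2 in macrophage-like cells favours neither explanation.

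Cardiomyocyte transcripts were lower in KO endothelial-like cells. Free RNA of a single library may account for it: het 1 held the highest share of these transcripts in 4 of 5 classes outside cardiomyocytes and erythroid cells, all but epicardial-like cells, where het 2 did, and in macrophage-like cells by less than the counting error. Mixed clusters kept out of the classes by the limits on cardiomyocyte markers held 14289 cells of het 1 and 180, 550 and 61 of het 2, KO 1 and KO 2. Among them clusters 2, 4 and 6, with endothelial, macrophage and epicardial profiles, held 2.48%, 2.45% and 2.43% of UMIs from those markers. Het 1 gave 92.3%, 92.0% and 94.0% of their cells. The shares compared here are thus those left after a cut on the same kind of transcript. In the endocardial-like clusters alone KO 1 was highest and the group means were 0.179% in het and 0.172% in KO, and the list's median was −0.0480 there (adjusted p = 0.393) and −1.96 in the vascular-like cluster, where the shares were 1.02% in het 1, 0.411% in het 2, 0.274% in KO 1 and 0.0967% in KO 2, so that het 2 also lay above both KO libraries, which a single library does not account for. Without het 1 the list's median was −0.251 (SE of members 0.103, camera adjusted p = 0.0052), where a median within 0.3 of 0 had been set in advance as arguing against genotype; it lay within that bound by less than its spread, a term added after the value was seen. The explanations cannot be told apart, because without het 1 a single het library is left to show the size of the difference.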
